A study of Mus musculus with 12 samples.

How the data were processed

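The study measured RNA in 12 mouse libraries, 3 for each of 4 groups made up of tissue (full colon or LPMC) and genotype (WT or Gpr15l KO), all from mice with DSS colitis. Per the labels' protocols, poly(A) RNA libraries that keep strand were prepared with a TruSeq kit, and the sequencer was an Illumina HiSeq. Per the submitters' processing notes, reads were handled with STAR and the build was GRCm38 (mm10). The version of STAR, the counting tool, the annotation, the strand setting and any filter are not given in the sources used here.

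The authors deposited a single table of whole-number read counts per Ensembl gene for all libraries, with no normalization. Columns were assigned to samples by the library names in the labels, and groups and replicate numbers were taken from the sample titles. The table holds 54109 gene identifiers and 0 rows that name no gene. Of these, 54042 matched the GENCODE M21 annotation of GRCm38, which gave symbols and coordinates, and 67 did not, holding at most 0.00333% of a library's counts. Gpr15l is listed as a synonym of 2610528A11Rik in the RefSeq table of the same build.

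Total counts were 45.4 to 140.7 M (M for 1e6 reads) per library. Even values were in excess, with 24184 entries of 2 in the table against 8495 entries of 1, and 66.6 to 76.6% of low counts were even. This is the pattern of read pairs whose mates were counted separately, so counting error is larger than the counts alone imply, and intervals from counts would be too narrow. No mitochondrial gene has counts in the table. Without a stated strand setting, reads of overlapping genes, such as Cpeb3 and March5, cannot be told apart, and members of near-identical families are uncertain. Pairs of replicates of a group differed far beyond sampling noise (chi-square per gene 85.8 to 685), so all 12 libraries were kept as separate. Every library held Ddx3y from the Y chromosome (24.9 to 81.8 CPM) and little Xist (0.228 CPM or less).

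Differential expression was tested in R 4.3.3 with edgeR 4.0.16 on the counts as deposited, with TMM factors, filterByExpr (minimum count 10), robust dispersion estimates and the quasi-likelihood F-test. The KO to WT comparison was fitted on the 6 libraries of each tissue, and the interaction and the LPMC to colon comparison on all 12 with a mean per group. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. Levels are TMM-scaled CPM, except that the plot of the deleted gene and Cdhr1 uses CPM of the library total. Gene lists for cell types and functions, 35 in all, were fixed before the data were examined, and 33 of them with at least 5 tested members were set-tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01. Camera with a correlation estimated per list and fry were alternatives. For LPMC against colon no set test was planned, and members are given as counts past the gene-level threshold.

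Genes were named by a rule fixed before the data were examined. It took the deleted gene and Gpr15, up to 10 genes per direction that passed without overlap between groups and with a mean log2 CPM of at least 1, or, with fewer than 5 of these, the 5 of lowest p in that direction, up to 4 members of each described list by lowest p, up to 10 genes of lowest p for the interaction and up to 3 members per list for LPMC against colon. Unnamed predicted genes and variable segments of antigen receptors were excluded from the parts not tied to a list. The limit of 4 members per list was also used for the interaction, for which the rule named none. Outside the rule, S100a9 in LPMC KO libraries, Epcam, Lrit2, Ccser2, Ghitm, Btaf1, Cpeb3, March5, Ide in colon and the kappa segments were chosen after their values were seen. An item that the rule names is not reported here. Median, mean and test differed in sign for endothelial markers in colon, for 4 lists in LPMC and for 4 in the interaction, none of them called.

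The edgeR and DESeq2 steps were tested on simulated counts with the libraries' own means and dispersions and 100 genes changed by each of 2 sizes. For colon (18757 genes), edgeR recovered 66 of 100 genes changed 4-fold and 2 of 100 changed 2-fold, with 5 false calls, and DESeq2 recovered 92 and 21, with 78 false calls. For LPMC (18876 genes), edgeR recovered 79 and 28, with 11 false calls, and DESeq2 94 and 51, with 87 false calls. For the interaction (20348 genes), edgeR recovered 36 and 2, with 5 false calls. For LPMC against colon (20391 genes), edgeR recovered 88 and 58, with 1 false call. A list shifted 2-fold with independent genes was called by camera in each of the 3 designs, with 0, 1 and 0 other lists called. This covers only lists whose members vary independently. In the colon libraries the estimated correlation of T cell markers was 0.709, so false list calls in the data cannot be judged from this simulation.

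Alternatives fixed before the data were examined were other scaling factors, no or a stricter filter on low counts, DESeq2 1.42.0, voom with sample quality weights, a minimum log2 fold change of 1, library sizes without immunoglobulin and haemoglobin genes, the replicate number as a block, a fit of all 12 libraries and leaving out each library in turn. Halved counts, and upper-quartile factors for the lists, were added after seeing the data.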

Results

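RNA was sequenced from mice in which acute colitis had been induced with dextran sulfate sodium (DSS), a polymer given to injure the colonic epithelium. Wild-type (WT) mice were compared with mice lacking Gpr15l (KO), the gene of a secreted ligand of the receptor Gpr15, which guides T cells to the colon. Material came from full colon and from LPMC, the usual abbreviation for lamina propria mononuclear cells, the immune cells released from the gut wall. The 12 libraries formed 4 groups of 3, namely colon WT, colon KO, LPMC WT and LPMC KO. Total counts ran from 45.4 M (M for 1e6 reads) in colon WT replicate 2 to 140.7 M in colon KO replicate 3. The labels do not state that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical in part. On log2 CPM (counts per 1e6 reads of the library), the first principal component carried 57.8% of the variance and parted colon from LPMC, and the next carried 10.2%.

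The deleted gene was examined first. Gpr15l is annotated as 2610528A11Rik (ENSMUSG00000096001), a protein-coding gene on the minus strand of chromosome 14 from 37102140 to 37114022 in GRCm38. Its reads were abundant in every WT library and close to absent in every KO library. Colon WT libraries held 80362, 15639 and 42849 counts, against 18, 14 and 20 in colon KO. LPMC WT libraries held 30584, 32405 and 18619 counts, against 4, 6 and 10 in LPMC KO. The mean level was 639 ± 305 CPM (SD, n = 3) in colon WT and 336 ± 37.2 CPM (SD, n = 3) in LPMC WT. The log2 fold change was -11.82 (SE 0.58) in colon, with an adjusted p of 0.00238, and -12.16 (SE 0.46) in LPMC, with an adjusted p of 0.00162, by edgeR's quasi-likelihood test. The WT to KO ratio of mean CPM, here of the library total, was 3399 in colon and 4133 in LPMC. The colon call was lost without colon KO replicate 2 (log2 fold change -11.99, adjusted p = 0.0568). With the replicate number as a block, the call was lost in colon (-11.74, adjusted p = 0.106) and in LPMC (-12.17, adjusted p = 0.145). Gpr15 itself was scarce, with 0 to 40 counts per colon library and 37 to 230 per LPMC library. Its log2 fold changes of -1.33 (SE 1.02) in colon and -0.54 (SE 0.52) in LPMC did not pass the test.

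**Figure D1:**
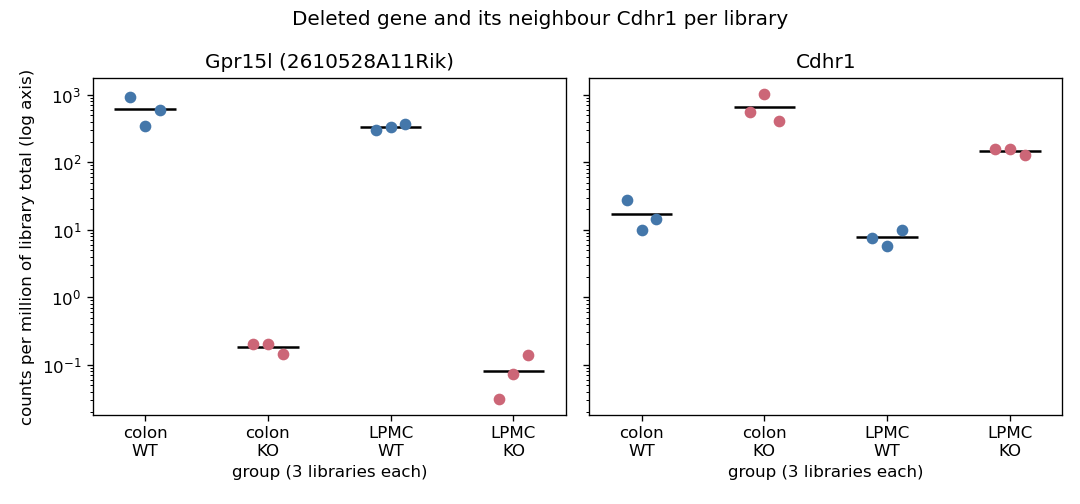
CPM of the library total (log axis) of Gpr15l, left, and of its neighbour Cdhr1, right, in the 4 groups. Each point is a library and each bar the mean of 3. Gpr15l lies between 297 and 936 CPM in WT and at 0.205 CPM or less in KO, while Cdhr1 lies between 5.79 and 27.2 CPM in WT and between 127 and 1036 CPM in KO.

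The comparison of KO with WT colon asked which transcripts differ in the inflamed tissue when Gpr15l is missing. Apart from the deleted gene, the clearest difference was in Cdhr1, a cadherin-related gene known from photoreceptors. Its level averaged 17.7 ± 9.15 CPM (SD, n = 3) in WT and 676 ± 413 CPM (SD, n = 3) in KO. The interferon-induced antiviral gene Bst2 averaged 126 ± 48.6 CPM in WT and 43.8 ± 5.69 CPM in KO, without overlap between the groups. It did not pass edgeR's test (adjusted p = 0.632). T cell markers, MHC class II genes and interferon response genes were lower as sets in KO colon, and smooth muscle markers were higher, by camera with a preset correlation. None of these shifts passed with an estimated correlation (adjusted p = 0.708).

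By edgeR, 1 of 19303 genes tested passed an adjusted p of 0.05 in colon, the deleted gene itself, and 0 were higher. At an unadjusted p under 0.05 there were 1504 genes where chance gives 965, and DESeq2 called 33 genes (19 higher, 14 lower). In 14.5% of genes the groups did not overlap, where chance gives 10%. Cdhr1 (ENSMUSG00000021803) lies on the minus strand of chromosome 14 from 37077857 to 37098347, beside the deleted gene. Lrit2 on its other side was at 2.75 (SE 1.02) and did not pass. The log2 fold change of Cdhr1, 5.25 (SE 0.61), missed the threshold by edgeR (adjusted p = 0.439) but passed with DESeq2 (adjusted p = 3.56e-19), with voom (0.0122) and in an edgeR fit of all 12 libraries (0.00537). Low p-values among higher genes were also those of Fgfbp3, a binding protein of fibroblast growth factors (2.38, SE 0.41), the transporter Slc12a8 (1.20, SE 0.22) and the zinc finger gene Zfp704 (0.97, SE 0.18). Among lower genes they were Bst2 (-1.52, SE 0.29), Id1, an inhibitor of differentiation induced by BMP signals (-1.20, SE 0.24), Rbm8a of the exon junction complex (-0.97, SE 0.20) and Arl5c (-1.42, SE 0.31). These genes from Fgfbp3 to Arl5c all had an adjusted p of 0.632 and did not pass.

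Of 33 gene lists fixed before the data were examined, 18 passed camera with a preset correlation in colon, 12 lower and 6 higher in KO. All 19 T cell markers had a negative log2 fold change, with a median of -1.09 (adjusted p = 1.2e-06). Their lowest p-values belonged to the T cell receptor gene Trbc2 (-1.42, SE 0.47), the adaptor Lat (-1.54, SE 0.55), Cd2 (-3.03, SE 1.09) and Cd3d (-1.64, SE 0.65). All 9 MHC class II genes, which present antigen to T cells, were negative too (median -1.28, adjusted p = 0.000361), among them H2-DMa (-1.28, SE 0.42), Cd74 (-1.25, SE 0.42) and H2-Ab1 (-1.19, SE 0.40). All 18 interferon response genes were negative (median -0.74, adjusted p = 8.5e-05), led by Isg15 (-1.63, SE 0.36), Oas1a (-0.62, SE 0.18) and Ifit3 (-1.31, SE 0.49). Adjusted over the list alone, 0 T cell markers, 6 MHC class II genes and 1 interferon response gene passed, all lower, and over all genes tested 0 did. These 3 calls held without any 1 of the 6 libraries, though the T cell median without colon WT replicate 1 was -0.49. Yet KO and WT libraries overlapped in mean log2 CPM for each of the 3 lists. Colon WT replicate 3 lay below colon KO replicate 3 for T cell markers (0.503 against 0.582) and MHC class II genes (4.901 against 5.189). The same held for interferon response genes (5.412 against 6.227). With an estimated correlation the adjusted p was 0.708 for each of the 18 lists, and none stayed called. Other splits of the same 6 colon libraries called up to 22 lists.

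Other leukocyte lists were lower in colon KO with the preset correlation. Colon KO replicate 2 stood apart from the other colon libraries on the second principal component (-85.03, against -10.69 to 52.45), with a mean log2 CPM of 1.66 for monocyte and macrophage markers, against 3.06 to 4.14, and of -1.001 for neutrophil markers, against 0.88 to 2.50. B cell markers had a median of -4.76 (adjusted p = 0.0192), with Cd79b at -5.35 (SE 2.00) and Cd79a at -5.26 (SE 2.05). Colon WT replicate 1 held 171 CPM of Cd79a, against 0.465 to 3.34 CPM in the other colon libraries, and without it the B cell median was 0.09 (adjusted p = 0.842). Plasma cell markers had a median of -1.67 (adjusted p = 0.0192), which became -0.06 (adjusted p = 0.295) without that library. Inflammatory cytokines (median -0.91, adjusted p = 0.0192; Tnf -1.02, SE 0.35), chemokines (median -0.76, adjusted p = 0.0302; Cxcl1 -1.18, SE 0.48) and leukocyte homing receptors (median -0.66, adjusted p = 0.0305; Cxcr4 -2.58, SE 1.03) were likewise lower. So were neutrophil markers (median -0.45, adjusted p = 0.0192; Ly6g -0.94, SE 0.22) and NK and cytotoxic genes (median -0.40, adjusted p = 0.0302; Gzma -1.97, SE 0.74). All 7 calls were lost without colon WT replicate 1 and without colon KO replicate 2, and those of cytokines, chemokines, neutrophil markers and NK genes also without colon WT replicate 2. Over the fits without 1 library the medians ran from -1.44 to -0.44 for cytokines, -1.29 to -0.35 for chemokines, -0.997 to 0.21 for homing receptors, -0.84 to 0.06 for neutrophil markers and -0.79 to -0.03 for NK genes. Adjusted p with an estimated correlation was 0.708 for all 7. Adjusted over the list alone, Ly6g passed and no other member of these 7 lists did.

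Colon KO replicate 2 also had the highest mean log2 CPM of the colon libraries for smooth muscle markers (6.06, against 3.57 to 5.54) and epithelial markers (10.77, against 9.63 to 10.37). Among epithelial and structural lists, epithelial repair genes were lower in colon KO (median -0.70, adjusted p = 0.00339), with Plaur, the urokinase receptor (-1.29, SE 0.32), Ly6a (-0.89, SE 0.24) and the growth factor Hbegf (-0.77, SE 0.22) the 3 members that passed when adjusted over the list alone. All 10 smooth muscle markers were positive (median 0.87, adjusted p = 0.00155), including Actg2 (1.97, SE 0.74) and Acta2 (0.95, SE 0.50). Extracellular matrix and protease genes (median 0.74, adjusted p = 0.0302; Tnc 1.11, SE 0.35), red blood cell markers (6 of 6 members positive, adjusted p = 0.0302), crypt stem and Wnt target genes (median 0.28, adjusted p = 0.0324; Lgr5 1.88, SE 0.80) and goblet cell genes (median 0.41, adjusted p = 0.0444; Muc2 0.69, SE 0.42) were also higher. Absorptive colonocyte genes stood at the threshold (median 0.76, adjusted p = 0.050), with 15 of 16 members positive, and were not called with DESeq2's size factors (adjusted p = 0.0601). Dissociation stress genes, a technical list of immediate early and heat shock genes, were lower (median -0.55, adjusted p = 0.0292; Junb -0.84, SE 0.29). Adjusted p with an estimated correlation was 0.708 for these lists as well. Without colon KO replicate 2 the calls of repair (median -0.59), smooth muscle (0.38), goblet (0.11) and absorptive genes (-0.30) were lost, and without colon WT replicate 1 those of smooth muscle (0.51), crypt (-0.0044) and goblet genes (0.37). Without colon WT replicate 2 the goblet (0.23), absorptive (0.29) and dissociation (-0.18) calls were lost, and without colon WT replicate 3 the matrix call (0.57). Without colon KO replicate 1 the red blood cell (0.20), crypt (0.31), matrix (0.65) and dissociation (-0.46) calls were lost, and without colon KO replicate 3 the crypt (0.12) and matrix (0.35) calls. The other 15 lists did not pass, among them regulatory T cell genes (median -0.86, adjusted p = 0.0945), monocyte and macrophage markers (median -0.19, adjusted p = 0.14) and proliferation genes (median -0.05, adjusted p = 0.373).

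**Figure D2:**
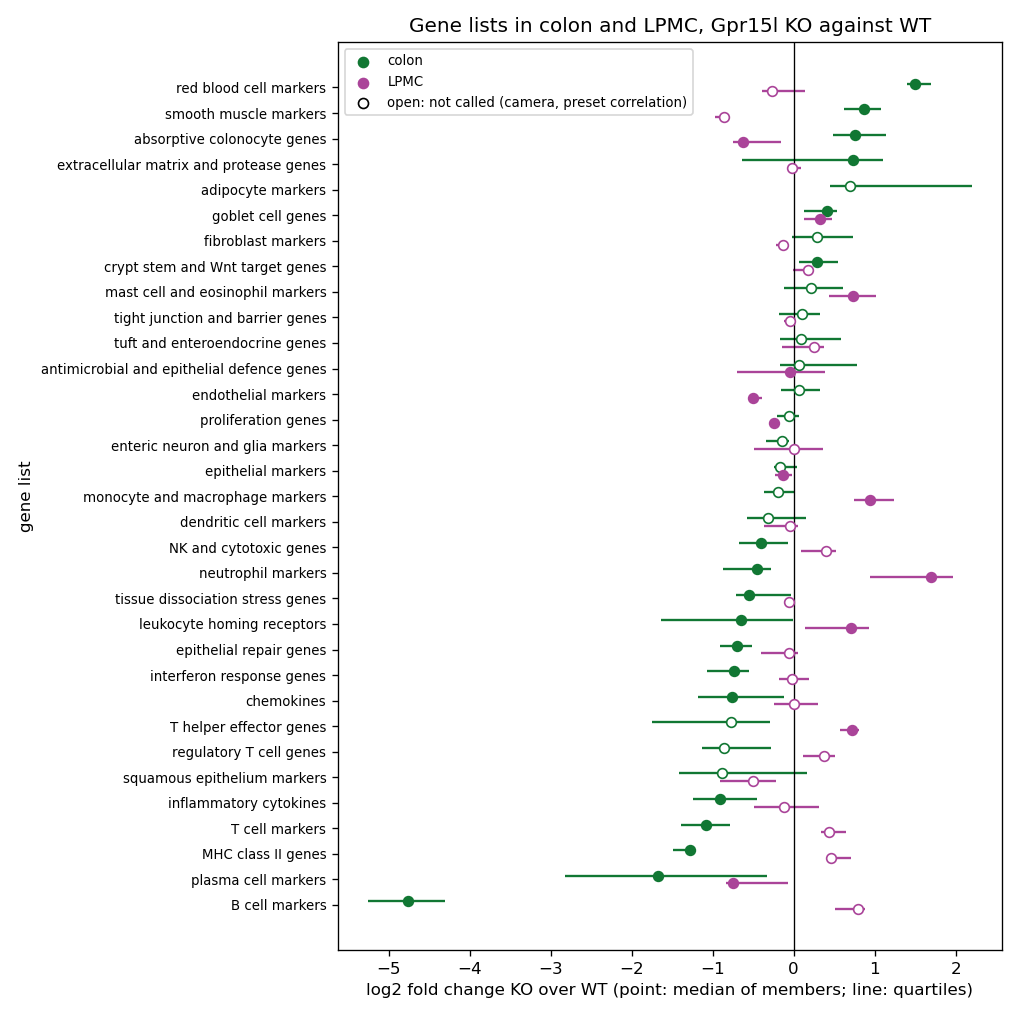
Change of 33 gene lists between KO and WT, as log2 fold change on the horizontal axis, in colon (green) and LPMC (purple). Points are medians over the measured members, lines span the quartiles, and filled points passed camera with a preset correlation. T cell markers sit at -1.09 in colon and 0.44 in LPMC, and neutrophil markers at -0.45 and 1.70.

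The same comparison in LPMC asked how the immune cells of the gut wall differ when Gpr15l is missing. Cdhr1 rose from 7.78 ± 2.03 CPM (SD, n = 3) in WT to 144 ± 16.1 CPM (SD, n = 3) in KO, and the deleted gene fell. Neutrophil markers and monocyte and macrophage markers were higher as sets in LPMC KO by camera with a preset correlation, but not with an estimated correlation (adjusted p = 0.849). Absorptive colonocyte genes, proliferation genes and endothelial markers were lower with the preset correlation, and likewise not with an estimated one (adjusted p = 0.849). The chemokine Cxcl1, which attracts neutrophils, averaged 135 ± 10.6 CPM in WT and 69.6 ± 12.6 CPM in KO, but did not pass edgeR's test (adjusted p = 0.998).

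By edgeR, 2 of 19426 genes passed in LPMC, Cdhr1 with a log2 fold change of 4.22 (SE 0.23, adjusted p = 0.00572) and the deleted gene. DESeq2 called 34 genes (8 higher, 26 lower), and 513 genes had an unadjusted p under 0.05 where chance gives 971. In 7.8% of genes the groups did not overlap, against 10% by chance. The Cdhr1 call was lost without LPMC WT replicate 1 or without LPMC KO replicate 1. It was also lost with the replicate number as a block, at a similar log2 fold change (4.24, adjusted p = 0.616). The next higher genes by p were the insulin-degrading enzyme Ide (0.92, SE 0.14), the Notch-modifying Lfng (0.54, SE 0.10), the sialic acid hydroxylase Cmah (0.76, SE 0.15) and Fgfbp3 (1.22, SE 0.24). The next lower genes were Clca4b (-1.59, SE 0.20), the acute-phase gene Saa1 (-1.55, SE 0.21), Cxcl1 (-0.95, SE 0.15) and the cornified envelope gene Sprr2a3 (-1.03, SE 0.18). Sprr2a3 belongs to a family of near-identical genes, so its reads are uncertain. The adjusted p was 0.745 for Clca4b, 0.751 for Saa1 and 0.998 for the other 6, so none of the 8 passed.

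**Figure D3:**
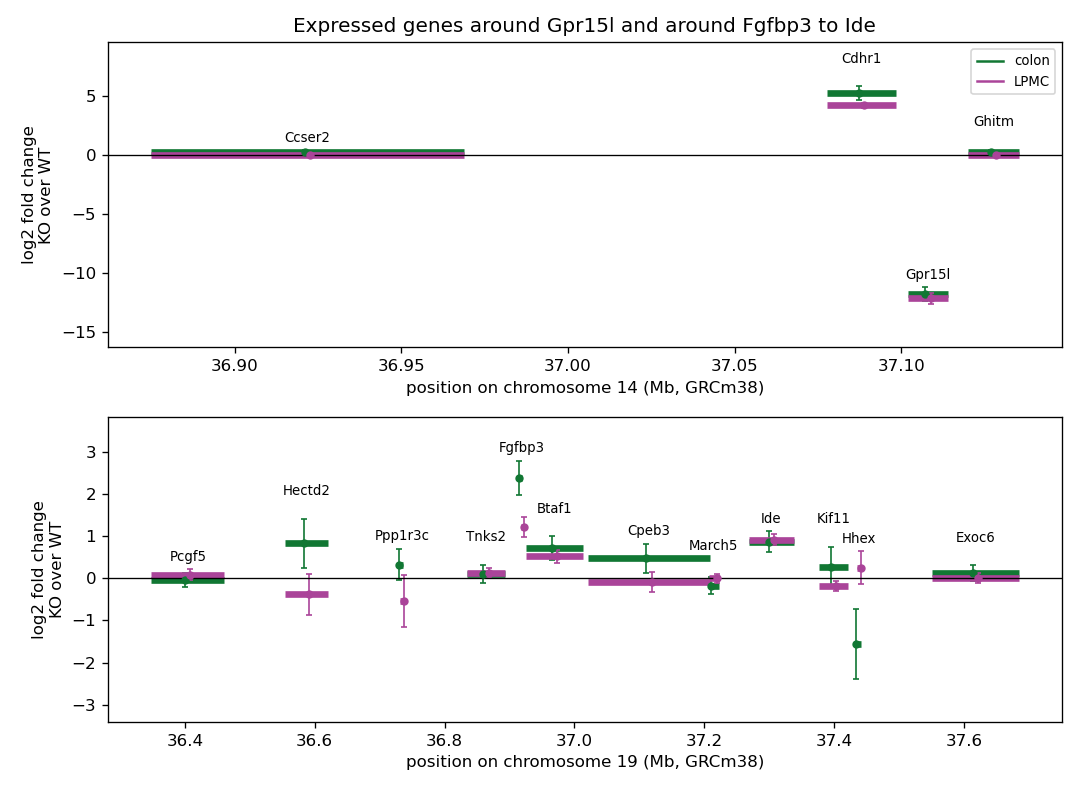
Log2 fold change of KO over WT (vertical axis) along chromosome 14 around Gpr15l, top, and along chromosome 19 from Pcgf5 to Exoc6, bottom, by position in Mb of GRCm38 (horizontal axis). Thick lines span the genes, points are estimates with standard errors for colon (green) and LPMC (purple); predicted genes, pseudogenes and genes tested in 1 tissue are left out. Cdhr1 lies at 5.25 in colon and 4.22 in LPMC, and Ide at 0.87 and 0.92.

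Of 32 lists tested in LPMC, 12 passed camera with a preset correlation, 6 higher and 6 lower. Neutrophil markers had a median of 1.70 (adjusted p = 0.000167), with 15 of 16 members positive, among them Stfa2l1 (2.25, SE 0.81), Mmp8 (1.99, SE 0.71) and Retnlg (1.75, SE 0.64). This call was lost without LPMC KO replicate 1, which held 302 CPM of S100a9 against 33.6 CPM in LPMC KO replicate 2 and 185 CPM in LPMC KO replicate 3. Monocyte and macrophage markers had a median of 0.94 (adjusted p = 1.79e-05), with Ms4a7 at 0.97 (SE 0.28) and the mannose receptor Mrc1 at 1.38 (SE 0.45). Mast cell and eosinophil markers (median 0.73, adjusted p = 0.00108) included the mast cell protease Mcpt1 (0.99, SE 0.23), which passed when adjusted over the list alone. T helper effector genes (median 0.72, adjusted p = 0.00341; Il5 0.92, SE 0.41, but Il22 -0.99, SE 0.47), homing receptors (median 0.70, adjusted p = 0.0278; Cxcr6 0.76, SE 0.23, but Itgae -0.90, SE 0.35) and goblet cell genes (median 0.32, adjusted p = 0.0404) were also higher. With an estimated correlation the adjusted p was 0.849 for every one of the 12 lists. Without LPMC KO replicate 1 the neutrophil median was 1.07. The monocyte call held without any 1 library. Yet LPMC KO replicate 2 had a lower mean log2 CPM for these markers (2.69) than the LPMC WT libraries (2.80 to 3.57). That library was also the lowest in LPMC for T cell markers (2.68, against 3.28 to 4.62). On the second principal component it lay with LPMC WT replicate 3 (-63.54 and -66.03), apart from the other LPMC libraries (11.66 to 43.62). Leaving it out gave 19 called lists. The mast cell call was lost without LPMC KO replicate 3 (median 0.39). The T helper call was lost without LPMC WT replicate 3 (0.55) or LPMC KO replicate 3 (0.38). The homing call was lost without LPMC WT replicate 2 (0.62) or 3 (0.51) or LPMC KO replicate 1 (0.46) or 3 (0.42), and the goblet call without LPMC WT replicate 1 (0.17) or 3 (0.35) or LPMC KO replicate 1 (0.33) or 2 (0.11). Other splits of the 6 LPMC libraries called up to 23 lists.

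Absorptive colonocyte genes were lower in LPMC KO (median -0.63, adjusted p = 1.79e-05). The carbonic anhydrase Car4 (-1.34, SE 0.33) and Hsd17b2 (-0.75, SE 0.18) passed when adjusted over the list alone. All 12 proliferation genes were negative by a small amount (median -0.24, adjusted p = 0.000159), with Birc5 at -0.41 (SE 0.16). All 10 endothelial markers were negative (median -0.51, adjusted p = 0.0007), with Cldn5 at -1.02 (SE 0.54). Epithelial markers (median -0.14, adjusted p = 0.00833; Krt20 -0.93, SE 0.28) and plasma cell markers (median -0.75, adjusted p = 0.0201; Mzb1 -0.85, SE 0.58) were lower. Antimicrobial and epithelial defence genes passed as lower with a median of only -0.04 (adjusted p = 0.022), their lowest p-values being those of Saa1, Reg3b (-0.83, SE 0.24) and Reg3g (-1.03, SE 0.30), and of these Saa1 passed when adjusted over the list alone. Adjusted p with an estimated correlation was 0.849 for these lists too. The proliferation call held without any 1 library. Without LPMC WT replicate 3 the absorptive (median -0.22), epithelial (-0.09) and antimicrobial (-0.08) calls were lost, and without LPMC KO replicate 3 the epithelial (-0.01) and antimicrobial (0.03) calls. The endothelial call was lost without LPMC WT replicate 1 (-0.21) or LPMC KO replicate 1 (-0.24), and the plasma cell call without LPMC WT replicate 1 (-0.50) or 2 (-0.51) or LPMC KO replicate 1 (-0.28) or 2 (-0.51). T cell markers (median 0.44, adjusted p = 0.0681), MHC class II genes (median 0.47, adjusted p = 0.18) and interferon response genes (median -0.02, adjusted p = 0.142) did not pass. Of the chemokines (median 0.01, adjusted p = 0.394), Cxcl1 alone passed when adjusted over the list alone, and over all genes tested it did not.

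Whether the KO effect differed between LPMC and colon was tested as an interaction. No single gene passed. By camera with a preset correlation, T cell, MHC class II, neutrophil, monocyte, B cell, homing receptor, T helper and NK lists were shifted upward in LPMC relative to colon. Smooth muscle markers and absorptive colonocyte genes were shifted downward. Other leukocyte lists were not called, namely cytokines (adjusted p = 0.0746), regulatory T cell genes (0.0926), chemokines (0.115), mast cell (0.341), dendritic cell (0.472) and plasma cell markers (0.744). With an estimated correlation no list was called (lowest adjusted p = 0.64). All 19 T cell markers had a positive difference of log2 fold changes (median 1.46, adjusted p = 5e-07), with Trbc2 at 2.03 (SE 0.70) and Cd3d at 2.27 (SE 0.85). All 16 absorptive colonocyte genes had a negative one (median -1.27, adjusted p = 0.000434), with Car4 at -1.29 (SE 0.63). By edgeR, 0 of 20989 genes passed, 985 had an unadjusted p under 0.05 where chance gives 1049, and DESeq2 called 3. Among the lowest p-values were those of Clca4b (-1.89, SE 0.35), the ETS factor Elk4 (0.71, SE 0.16), Igsf23 (1.11, SE 0.27), the retinol dehydrogenase Rdh16 (-1.02, SE 0.24), Plaur (1.66, SE 0.40), AU020206 (1.60, SE 0.39), Bcl3 (1.01, SE 0.25), Ptk6 (-1.13, SE 0.28) and the flagellin receptor Tlr5 (-1.48, SE 0.40), all with an adjusted p of 0.902. Plaur passed when adjusted over the repair list alone.

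Of 33 lists tested for the interaction, 15 passed camera with a preset correlation, 10 with a positive and 5 with a negative difference. MHC class II genes (median 1.79, adjusted p = 0.000229), neutrophil markers (median 2.10, adjusted p = 0.000347; S100a9 2.78, SE 1.34) and monocyte and macrophage markers (median 1.10, adjusted p = 0.000347; C1qa 1.78, SE 0.93) were among the positive ones. Smooth muscle markers (median -1.70, adjusted p = 0.000768; Actg2 -2.97, SE 1.30) and adipocyte markers (median -1.88, adjusted p = 0.00358; Plin1 -5.13, SE 2.06) were among the negative ones. B cell markers had a median of 5.67 (adjusted p = 0.00172), which was 0.61 without colon WT replicate 1, where the call was lost, as it was without colon KO replicate 2 (5.19). With an estimated correlation the adjusted p was 0.64 for each of the 15 lists. The T cell, MHC class II and adipocyte calls held without any 1 of the 12 libraries. For adipocyte markers, colon KO replicate 3 stood apart in mean log2 CPM (2.11, against -1.36 to -0.10 in the other colon libraries). Without colon KO replicate 2 the neutrophil (median 1.60), monocyte (0.69) and absorptive (-0.40) calls were lost, and without colon WT replicate 1 the smooth muscle call (-1.37). The interferon call was lost without colon WT replicate 2 (0.40) or colon KO replicate 1 (0.47). Homing and T helper calls were lost without colon WT replicate 1 (0.33 and 0.58), colon KO replicate 2 (0.78 and 0.96) or LPMC KO replicate 3 (1.05 and 0.85). NK, endothelial, red blood cell and repair calls were each lost without any of 5 or more libraries. Of 100 regroupings of the genotype labels within tissues, 35 called as many lists.

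The LPMC and colon libraries themselves differed widely, which shows what each kind of sample held. All 19 T cell markers and all 13 NK and cytotoxic genes were higher in LPMC, for example Cd3g (log2 fold change 3.17, SE 0.35) and Fasl (4.63, SE 0.37). Plasma cell transcripts were higher in 9 of 11 members, with Igha, the heavy chain of IgA, at 5.72 (SE 0.63) and Jchain at 5.95 (SE 0.67). Of the enteric neuron and glia markers 9 of 10 were lower in LPMC, with Gfap at -5.92 (SE 0.48) and Sox10 at -5.45 (SE 0.47). The immediate early and heat shock genes induced by tissue dissociation were higher in 12 of 13 members, with Nr4a1 at 6.56 (SE 0.31). All these genes passed edgeR's test, which called 10549 of 20989 genes, 5325 higher and 5224 lower in LPMC. With upper-quartile factors 4443 were higher and 6365 lower.

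LPMC libraries also held much epithelial RNA. Epcam, an epithelial adhesion molecule, stood at 964 to 1409 CPM in LPMC against 1335 to 2433 CPM in colon. Of the absorptive colonocyte genes 6 of 16 were lower and 1 higher, with Aqp8 at -6.59 (SE 0.78) and Car4 at -5.43 (SE 0.38), and of the epithelial markers 8 of 14 were lower, with Krt20 at -3.07 (SE 0.28). Crypt genes were higher in LPMC in 8 of 12 members, with the stem cell receptor Lgr5 at 3.66 (SE 0.52) and Sox9 at 2.79 (SE 0.26). Endothelial markers were higher in 8 of 10 members (Kdr 2.82, SE 0.30), fibroblast markers in 8 of 11 (Col14a1 5.13, SE 0.58) and red blood cell markers in 6 of 7 (Hbb-bs 6.31, SE 0.67). Interferon response genes were lower in 12 of 18 members and higher in 1, with Oas1a at -1.64 (SE 0.11) and Mx1 at -2.29 (SE 0.22). Of the antimicrobial genes 6 were lower and 3 higher, with Saa1 at -6.21 (SE 0.30). Myeloid markers were mixed, since 5 of 16 neutrophil markers were higher and 2 lower, and 2 of 16 monocyte and macrophage markers were higher and 1 lower. Adjusted over the list alone, the counts were the same for T cell, NK, plasma cell, neuron and glia, dissociation, crypt, absorptive, endothelial, fibroblast, antimicrobial and neutrophil lists. By that measure 7 of 7 red blood cell markers were higher, 9 epithelial markers were lower, 1 interferon response gene was higher and 13 were lower, and 1 monocyte and macrophage marker was higher and 0 were lower. Gpr15 was higher in LPMC (2.75, SE 0.61, adjusted p = 0.00344).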

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

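The tests on Cdhr1, on the stretch of chromosome 19 and on the B cell and T cell lists without a library were chosen after the results were seen; the covariate test and the counts of other splits were not.

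The 10 splits of 6 libraries are too few for a share under 0.05. The real split called 1 gene in colon (highest other 0) and 2 in LPMC (highest other 0). It called 18 lists in colon, where 4 of 10 splits gave as many (highest other 22), and 12 in LPMC, where 6 of 10 did (highest other 23). For LPMC against colon chance can be excluded, since 1 of 100 splits, the real one, gave 10549 genes and the highest other 22.

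Differences between tissues drew attention to 15 lists, whose KO effect differed between LPMC and colon by camera on the interaction term with a preset correlation, but not with an estimated one (adjusted p = 0.64 for each). The median difference of log2 fold changes (LPMC minus colon) was 1.46 for T cell markers, 1.79 for MHC class II genes, 2.10 for neutrophil markers, 1.10 for monocyte and macrophage markers, 0.69 for interferon response genes and 5.67 for B cell markers (0.61 without colon WT replicate 1). It was 1.13 for leukocyte homing receptors, 1.13 for T helper effector genes, 0.63 for NK and cytotoxic genes and 0.52 for epithelial repair genes. It was -1.27 for absorptive colonocyte genes, -1.70 for smooth muscle markers, -1.88 for adipocyte markers, -0.56 for endothelial markers and -1.68 for red blood cell markers. As many lists were called in 35 of 100 regroupings of the libraries (the highest of the others called 24), so chance is not excluded for the 15. For single genes 0 were called, so all 100 regroupings called as many whatever the data (the highest of the others called 3), and the count tells nothing.

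By camera with a preset correlation 9 of 14 leukocyte lists were called lower in KO colon (adjusted p = 0.708 for each with an estimated correlation), and of these only plasma cell markers were called lower in LPMC; monocyte (adjusted p = 0.14), dendritic cell (0.106), regulatory T cell (0.0945), T helper (0.14) and mast cell (0.529) lists were not called in colon. Lymphoid tissue in colon WT replicate 1 may account for the B cell list, which was no longer called without that library (adjusted p = 0.8424). The T cell list was still called with the preset correlation (adjusted p = 0.006818). With an estimated correlation it was called neither with that library (adjusted p = 0.708) nor without it (0.924), so that condition cannot decide. Its median moved from -1.09 to -0.49 without that library, so the explanation stays open for the T cell list. With the log2 level of the pan-leukocyte gene Ptprc as a covariate, 3 of the 9 leukocyte lists called lower in colon stayed called lower, which neither excludes nor requires a differing overall share of leukocyte RNA, and without colon KO replicate 2, the library lowest in neutrophil (-1.001), monocyte (1.66) and T cell (-0.67) markers by mean log2 CPM, 2 of the 9 were still called (T cell markers and MHC class II genes). An effect of Gpr15l on leukocytes in the colon is also open, and these data do not separate it from uneven sampling of the gut wall.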

How the results depend on the processing

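All settings here were fixed before the data were examined, except halved counts and upper-quartile factors for the lists. Leaving out 1 library gave 0 to 1 called genes in colon (0 without colon KO replicate 2), 1 to 2 in LPMC (1 without LPMC WT replicate 1 or LPMC KO replicate 1), 0 for the interaction and 9451 to 10790 for LPMC against colon. DESeq2 called 33 genes in colon, 34 in LPMC and 3 for the interaction, and in simulated counts it made many false calls. Voom called 2 genes in colon, the fit of all 12 libraries 2, and no filter on low counts gave 4 in LPMC. A minimum log2 fold change of 1 left 6052 of the 10549 genes for LPMC against colon. Upper-quartile factors called 10808 (4443 higher, 6365 lower), and moved the median of all genes by -0.134. Every setting gave Gpr15l a log2 fold change below -11, with -12.11 to -11.40 in colon and -12.75 to -11.63 in LPMC over the fits without 1 library (adjusted p up to 0.0568).

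The labels do not say whether a replicate number marks a mouse. Same-numbered KO and WT libraries deviated from their group means with correlations of 0.029, -0.155 and -0.117 in colon and 0.268, -0.069 and -0.277 in LPMC. Same-numbered colon and LPMC libraries of a genotype gave 0.064 to 0.303, all positive though not all above the bound of 0.1. Those with different numbers gave -0.257 to 0.191, so a shared mouse is a real possibility. The tissues were treated as independent, and results that combine both tissues depend on this. With the replicate number taken as a mouse, the interaction called 0 genes, and 17 lists by camera with a preset correlation. With the replicate block, 0 genes were called in colon and 0 in LPMC, with Gpr15l at -11.74 (adjusted p = 0.106) and -12.17 (adjusted p = 0.145). Fewer residual degrees of freedom are part of that fit's construction.

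The 18, 12 and 15 list calls in colon, LPMC and the interaction became 0, 0 and 0 with an estimated correlation, with fry and with fry in either direction. Without 1 library they ranged from 9 to 21, from 10 to 19 and from 9 to 19; the counts furthest from those above came without colon WT replicate 1 (9 in colon, 9 for the interaction), colon KO replicate 2 (9), colon WT replicate 2 (11) and LPMC KO replicate 2 (19). In colon, some list calls were lost with a change of direction by camera with a preset correlation, and none was called in the other direction. For leukocyte homing receptors (-0.997 to 0.21) the test, not the median of -0.52, turned without colon KO replicate 2 (adjusted p = 0.904). Neutrophil markers ran from -0.84 to 0.0564, the highest without colon KO replicate 2 (adjusted p = 0.904). B cell markers ran from -6.34 to 0.0854, the highest without colon WT replicate 1 (adjusted p = 0.842). In 86 further fits a list called in neither changed sign. The causes were not tested.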

Other observations

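The tests on Cdhr1 and on chromosome 19 were chosen after the results were seen. Some genes differed in the same direction in both tissues. At an unadjusted p under 0.05 in each tissue, 16 genes were higher and 31 lower in KO. Of the genes tested in both, 18051 lie on assembled chromosomes. By chance 18.0 in the same direction would follow if the tissues are independent, and 5 genes lay in opposite directions. Cdhr1 is among the higher genes and the deleted gene among the lower ones. Genes with the same direction in both tissues also included Fgfbp3, Btaf1 and Ide, which lie together on chromosome 19. A further 4 were kappa variable segments (Igkv4-53, Igkv5-48, Igkv12-41, Igkv8-28) on chromosome 6, which were lower.

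Cdhr1 was higher in KO in 6 of 6 KO libraries, next to the deleted gene on the same strand. It had the lowest p of all higher genes in both tissues, and whether it responds in trans was not tested. Lrit2, next past Cdhr1 on the plus strand, was at 2.75 (SE 1.02, unadjusted p = 0.0299) in colon and too low to test in LPMC, while Ghitm (0.23, SE 0.22 in colon) and Ccser2 (0.24, SE 0.19) did not pass. Transcription from the altered locus running into Cdhr1 may explain the rise. Cdhr1 in KO and Gpr15l in WT stood at 676 and 639 CPM in colon and at 144 and 336 CPM in LPMC. CPM are not corrected for transcript length (828 bases of exon for Gpr15l), so levels of different genes cannot be set against each other. Ratios between tissues within each of these genes do not depend on length. Their colon to LPMC ratios differed by 1.913 standard errors, close to the bound of 2 set for this test. The log2 ratio was 2.06 (SE 0.49) for Cdhr1 in KO, 0.82 (SE 0.42) for Gpr15l in WT and 1.10 (SE 0.47) for Cdhr1 in WT. The KO ratio of Cdhr1 was no closer to that of Gpr15l than to its own in WT, so the test does not favour this hypothesis, which stays open. Flanking DNA of another strain could not be judged either, since 0% of 37 expressed genes within 5 Mb, without Cdhr1 and the deleted gene, had p under 0.05 in both tissues against 0.278% elsewhere, too few to tell.

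Fgfbp3 (36917550 to 36919615), Btaf1 (36926079 to 37012752) and Ide (37268743 to 37337852) on chromosome 19 were all higher in KO in both tissues at unadjusted p-values. Fgfbp3 was at 2.38 (SE 0.41) and 1.22 (SE 0.24), Btaf1 at 0.71 (SE 0.28) and 0.52 (SE 0.15), and Ide at 0.87 (SE 0.25) and 0.92 (SE 0.14), in colon and LPMC. Shuffled gene orders held 3 such genes within 0.5 Mb at a share of 0.006499, so independent placement rarely gave such a cluster. The window and the count were set after the cluster was seen, and linked genes such as the kappa segments also cluster. Chance is therefore not excluded. A single unbroken copied segment from Fgfbp3 through Ide is argued against by March5, which lies between them and was below Ide by 5.143 standard errors in LPMC. For a dose difference of Ide alike in both tissues, its change was compared between them and differed by 0.1326 standard errors. Ide was picked for low p-values in both tissues, and any effect shared by the tissues would give such a value. The test therefore cannot decide, and a dose difference stays open. Copy number in this stretch is known to vary among C57BL/6J mice, but the labels give no strain.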
